A study of Mus musculus with 9 samples.

How the data were processed

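Gene expression was measured in 9 libraries of poly(A) RNA from whole mouse lungs, 3 libraries in each of 3 groups. The groups PBS_PBS, PBS_HDM and Pam2ODN_HDM, and the library numbers 1 to 3, were taken from the sample titles. Per the labels' protocols, lungs were perfused with PBS, kept in RNAlater and homogenised, RNA was extracted with a column kit, and libraries were made with a stranded poly(A) protocol and sequenced as paired ends on an Illumina NovaSeq instrument. Nothing beyond the titles says that the libraries of a group came from separate animals, so p-values measure the spread between these samples.

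The deposited gene table held 1 column of counts and 1 column of FPKM per library for 31585 genes. The counts were whole numbers and, per the submitters' processing notes, came from a pipeline that named cutadapt, FastQC, HISAT2 and StringTie with the genome build GRCm38. The versions, the program that made the counts, and whether counting used the strand are not given in the sources used here, so counts may be estimates derived from coverage rather than tallies of reads. The deposited FPKM values, which relate each gene's fragments to its length and to the library total, were used as they stood. KEGG terms were those listed per gene in the deposited table. Every per-library column had a sample, and 0 rows lacked a gene. Each library's counts and FPKM were checked against each other. Deviations from the mean of all libraries correlated at r of 0.966 or more within a library and at 0.570 or less between libraries, across genes. The positions given are those of the table, on GRCm38. Of the genes, 31498 were found in GENCODE release M21, 28599 (90.8%) with the same start and end, and transcript lengths for 16406 (99.9%) of the tested genes came from that annotation. Overlapping genes and close paralogs, such as Saa1 and Saa2, Mt1 and Mt2, Ear1 and Ear2, Orm2 and the haemoglobin genes, may share reads, and their values are uncertain.

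The test for single genes was fixed before the data were examined as limma on log2(FPKM + 0.1). Because the table also held counts, the test used here is edgeR's quasi-likelihood test on the deposited counts, and the limma test is kept as an alternative. Genes with an FPKM of at least 0.5 in at least 3 libraries were tested, 16425 in number. Libraries were scaled by TMM factors, which were 0.883 for Pam2ODN_HDM 2, 0.936 for PBS_HDM 1 and 0.992 to 1.05 for the others, and all 9 libraries entered 1 fit with a mean per group. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no fold minimum, and "rose" or "fell" is written of called genes. Log2 fold changes are given with their standard errors (SE) and group values as mean FPKM with SD over 3 libraries. The SE of a gene by edgeR is approximate. It was computed as the size of the log2 fold change divided by the square root of the test's F statistic. Where a group had 0 counts in all its libraries, the fold was computed against a floor of 3 counts per library. Floors cover counting error only.

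The lists of genes, 39 in number, were also fixed before the data were examined, and 38 had at least 3 tested members. Some were set as checks on dissection, blood, handling, time of day and animals, not on the treatment. These were the lists of red blood cell, cardiac muscle, adipose and mesothelial, immediate early, circadian, glucocorticoid, mitochondrial and sex-linked genes. The 38 lists were tested with limma's camera on log2(FPKM + 0.1), with a preset correlation between genes of 0.01 and adjustment over the lists. They were tested again with the correlation estimated for each list. For each list the number of called members is given with adjustment over all genes and adjusted over the list alone. The genes named are the 12 largest rises and the 12 largest falls among called genes with complete separation of the groups and a mean FPKM of at least 1 in the higher group, up to 4 members with the lowest adjusted p of each list described, and a fixed set of genes of type 2 inflammation. Unnamed gene models and immunoglobulin or T cell receptor segments were not eligible. Any other gene named was chosen after its values were seen, and the text says so. The values of 1 named gene are not reported here.

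The 3 comparisons were PBS_HDM against PBS_PBS, Pam2ODN_HDM against PBS_HDM, and Pam2ODN_HDM against PBS_PBS. The share of genes that moved in opposite directions in the first and second comparison was computed with 20 simulated data sets for each of 2 scenarios, because the comparisons share libraries. Alternatives fixed in advance were other pseudocounts, filters and scalings, a fit of only the compared groups, a replicate block, a 2-fold minimum, robust and untrended spread, and omission of each library. Added after the data had been seen were DESeq2, limma on FPKM as first fixed, no scaling, voom with quality weights, removal of each library's trend with transcript length, and omission of 2 pairs of libraries. Replicates differed by far more than counting noise, with a chi-square per degree of freedom of 40.3 to 403, so none was treated as a duplicate.

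The edgeR test was tested on simulated data made from the real means, with 50 genes changed at each of 4 sizes among 16425. For PBS_HDM against PBS_PBS, 0% of 1.5-fold, 38% of 2-fold, 80% of 4-fold and 96% of 8-fold changes were recovered, with 3 false calls of 110. For Pam2ODN_HDM against PBS_HDM the shares were 0%, 38%, 92% and 90%, with 10 false calls of 120. For Pam2ODN_HDM against PBS_PBS they were 2%, 30%, 80% and 96%, with 8 false calls of 112. These shares hold for the simulated changes only. Of the 1830 genes called in the real PBS_HDM against PBS_PBS comparison 851 changed at least 2-fold and the others by less. The software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.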

Results

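Messenger RNA was sequenced from whole lungs of naive BALB/c mice in 3 groups of 3 libraries. Mice of the group PBS_PBS received only PBS, as their titles give it. In PBS_HDM, a PBS aerosol was followed 7 days later by 100 µg of house dust mite (HDM), an allergen source, placed in the trachea. In Pam2ODN_HDM, the aerosol given 7 days before the same HDM dose held 4 µM Pam2CSK4, a synthetic lipopeptide that activates Toll-like receptor 2, and 1 µM of a synthetic oligodeoxynucleotide (ODN) in 8 ml of PBS, nebulised over about 40 minutes. The interval between HDM and lung collection and the sex of the mice are not given in the sources used here. Total counts were 64062399, 52812888 and 64838401 for PBS_PBS 1, 2 and 3, 65765844, 63454607 and 53840003 for PBS_HDM 1, 2 and 3, and 63926984, 62414294 and 55348009 for Pam2ODN_HDM 1, 2 and 3. Of 31585 genes, 16425 were expressed highly enough to be tested.

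Some libraries differed in ways their groups do not explain. Genes with long transcripts were low relative to the mean of all libraries in Pam2ODN_HDM 2 and PBS_HDM 1, with a Spearman rho of deviation against transcript length of -0.43 and -0.29 across genes, against -0.04 to 0.28 in the other 7 libraries. The mitochondrially encoded genes took 1.22% and 1.58% of the counts in those libraries and 2.09% to 2.95% in the others. Xist, the RNA that silences 1 X chromosome in female cells (chromosome X, 103460366 to 103483254), had 8 counts in PBS_HDM 3 and 5 in Pam2ODN_HDM 3, against 11483 to 34396 in the other 7. Counts of the Y-linked genes Kdm5d, Uty, Ddx3y and Eif2s3y summed to 8580 in PBS_HDM 3 and to 0 in each other library, Pam2ODN_HDM 3 included.

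**Figure D1:**
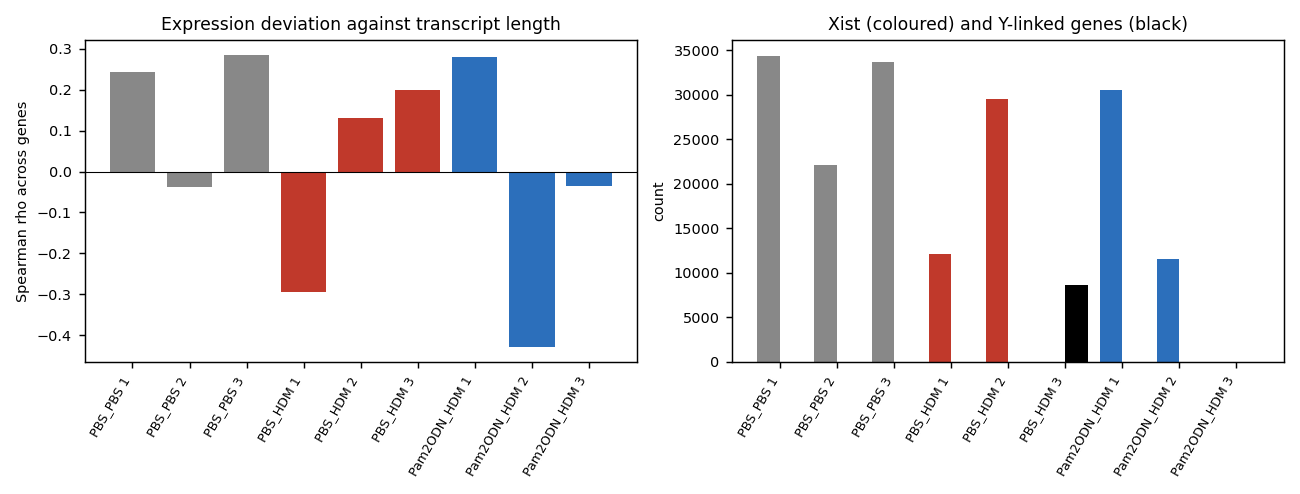
Left, Spearman rho across genes between each library's expression deviation and transcript length, 1 bar per library, lowest in Pam2ODN_HDM 2 (-0.43) and PBS_HDM 1 (-0.29). Right, counts per library of Xist (bars in the group colours) and of 4 Y-linked genes summed (black), with 8 and 5 Xist counts in PBS_HDM 3 and Pam2ODN_HDM 3 and 8580 Y-linked counts in PBS_HDM 3.

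The comparison of PBS_HDM with PBS_PBS asked what HDM does to the lung transcriptome. Of 38 gene lists, that of acute inflammation had the highest median rise. Csf3, which encodes granulocyte colony-stimulating factor (ENSMUSG00000038067, chromosome 11, 98701263 to 98703629), had 0 counts in PBS_PBS and an FPKM of 4.79 ± 1.32 (SD, n = 3) in PBS_HDM, at least 158-fold higher. Saa3, a serum amyloid A gene (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700), went from 1.15 ± 0.155 to 752 ± 186 FPKM (SD, n = 3), a log2 fold change of 9.45 ± 0.75 (SE). Cxcl3, a neutrophil-attracting chemokine (ENSMUSG00000029379, chromosome 5, 90786103 to 90789600), rose by 7.86 ± 0.60 on the log2 scale from 0.105 ± 0.0722 to 23.8 ± 10.3 FPKM (SD, n = 3). In all, 1830 genes were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1205 higher and 625 lower in PBS_HDM, with 622 and 229 of them changed at least 2-fold. That split was 65.8% higher by edgeR, 59.4% by limma on FPKM and 55.3% by limma with quantile scaling. The groups were completely separated for 6854 genes (41.7%, where chance gives 10%). The count of higher genes was 655, 681 and 627 without PBS_PBS 1, 2 and 3, 680 without PBS_HDM 2 and 2006 without Pam2ODN_HDM 2, which shares the estimate of spread. The count of lower genes was 200, 234 and 187 without PBS_PBS 1, 2 and 3, 314, 190 and 305 without PBS_HDM 1, 2 and 3, and 1457 without Pam2ODN_HDM 2.

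All 16 measured acute inflammatory cytokines and chemokines rose with HDM, also 16 adjusted over the list alone, with a median log2 fold change of 4.79. Cxcl1, another neutrophil chemokine (ENSMUSG00000029380, chromosome 5, 90891241 to 90893115), went from 1.19 ± 0.409 to 52.1 ± 7.95 FPKM (SD, n = 3), and Ccl2, which attracts monocytes, from 1.46 ± 0.217 to 47.1 ± 5.55. Il1b rose from 19.0 ± 5.62 to 217 ± 45.0 FPKM (SD, n = 3), and Il6, a cytokine of the acute phase (ENSMUSG00000025746, chromosome 5, 30013114 to 30019981), from 0.0706 ± 0.0076 to 5.62 ± 2.92. Among the largest rises outside that list were Acod1, the enzyme that makes itaconate in activated macrophages, from 0.341 ± 0.0962 to 54.7 ± 17.0 FPKM (SD, n = 3), the amino acid oxidase Il4i1 at 6.20 ± 0.35 (log2, SE) and the fatty acid receptor Gpr84 at 5.81 ± 0.33. Of 13 epithelial antimicrobial and barrier genes 11 rose, also 11 adjusted over the list alone, with a median of 1.92. Lcn2, which binds bacterial siderophores, went from 20.8 ± 0.574 to 851 ± 163 FPKM (SD, n = 3), and Il1rn, the antagonist of the interleukin 1 receptor, from 2.27 ± 0.0802 to 55.0 ± 6.37. Cfb, complement factor B, went from 19.5 ± 1.57 to 121 ± 6.90 FPKM (SD, n = 3). The camera test gave adjusted p = 7.91e-27 for the acute list and 1.63e-13 for the antimicrobial list, and adjusted p = 0.027 and 0.0338 with an estimated correlation. With genes at 0 in PBS_PBS set to their lower bound, the medians were the same.

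Chemokines of type 2 immunity also rose. Of 10 measured type 2 cytokines and chemokines, 5 rose (6 adjusted over the list alone), with a median log2 fold change of 1.77. Ccl22 (ENSMUSG00000031779, chromosome 8, 94745590 to 94751699) and Ccl17 (ENSMUSG00000031780, chromosome 8, 94810453 to 94812036), neighbouring genes for chemokines that attract T helper 2 cells, went from 4.04 ± 0.553 to 28.8 ± 3.18 and from 1.60 ± 0.146 to 30.4 ± 8.68 FPKM (SD, n = 3). The alarmin Il33 (ENSMUSG00000024810, chromosome 19, 29925114 to 29960718) rose from 17.1 ± 2.65 to 56.9 ± 8.68 FPKM (SD, n = 3). The eosinophil chemokine Ccl11 (ENSMUSG00000020676, chromosome 11, 82057823 to 82062955) rose from 3.90 ± 0.0936 to 17.8 ± 2.96. Their log2 fold changes were 1.83 ± 0.15 and 2.28 ± 0.23 (SE), with adjusted p = 0.000109 and 0.000293 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Retnla, a secreted protein of alternatively activated macrophages and airway epithelium (ENSMUSG00000061100, chromosome 16, 48842551 to 48844461), rose from 44.6 ± 8.88 to 1655 ± 479 FPKM (SD, n = 3), a log2 fold change of 5.32 ± 0.55 (SE, edgeR with Benjamini-Hochberg adjusted p = 0.000381). The type 2 list was past camera's test with adjusted p = 5.2e-06, and adjusted p = 0.0338 with an estimated correlation. Il4, Tslp, Ccl24 and Clca1 were not called, with log2 fold changes of -0.49, -0.23, 1.31 and 2.44 and adjusted p = 0.435, 0.656, 0.161 and 0.0581 by the same edgeR test with Benjamini-Hochberg adjustment.

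Several cytokines central to type 2 and other helper responses were near or under the detection filter in whole lung. Il5 was at 0.212 ± 0.220 FPKM in PBS_PBS, 0.283 ± 0.166 in PBS_HDM and 0.136 ± 0.0980 in Pam2ODN_HDM (SD, n = 3), and Il13 at 0, 0.0159 ± 0.0275 and 0.0106 ± 0.0184. Ifng was at 0.227 ± 0.104, 0.246 ± 0.120 and 0.324 ± 0.202 FPKM in the same order of groups (SD, n = 3), and Il17a at 0, 0.172 ± 0.219 and 0.237 ± 0.126. The goblet cell mucin Muc5ac was at 0.133 ± 0.0664, 0.384 ± 0.117 and 0.253 ± 0.0776 FPKM (SD, n = 3), and the eosinophil peroxidase gene Epx at 0.0205 ± 0.0208, 0 and 0.0157 ± 0.0271. These 6 genes lay under the filter and their differences were not tested, and Il25 was not analysed here.

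Interferon-stimulated genes rose as a group with HDM. All 20 measured genes of the type I interferon response rose, also 20 adjusted over the list alone, with a median log2 fold change of 1.77. Rsad2, an antiviral enzyme, went from 1.59 ± 0.137 to 10.1 ± 2.21 FPKM (SD, n = 3). Of 21 interferon-gamma response genes 11 rose (13 rose and 1 fell adjusted over the list alone), with a median of 0.94, among them Cxcl10, which attracts activated T cells, from 0.687 ± 0.186 to 18.3 ± 4.16 FPKM (SD, n = 3). Members of the Toll-like receptor and NF-kB pathway rose in 12 of 20 cases (15 rose and 1 fell adjusted over the list alone), with a median of 0.71, and the receptor gene Tlr2 went from 9.75 ± 1.58 to 42.4 ± 4.54 FPKM (SD, n = 3). The camera test gave adjusted p = 2.24e-18, 5.13e-08 and 1.61e-09 for these 3 lists, and adjusted p = 0.108 for each with an estimated correlation, so that their calls rest on the preset correlation.

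Neutrophil and airway mucus genes were higher after HDM. Of 13 neutrophil markers 5 rose (8 adjusted over the list alone), with a median log2 fold change of 1.51, and the chemokine receptor Cxcr2 went from 8.06 ± 2.05 to 48.1 ± 11.9 FPKM (SD, n = 3). Of 10 genes of mucous metaplasia 4 rose (5 adjusted over the list alone), with a median of 1.09. Slc26a4, the anion exchanger pendrin, went from 0.478 ± 0.184 to 17.0 ± 2.52 FPKM (SD, n = 3) and the airway mucin Muc5b from 2.58 ± 0.860 to 8.57 ± 1.71. Alternative macrophage activation genes rose in 5 of 14 cases (6 adjusted over the list alone), with a median of 0.74. Of 12 genes responsive to glucocorticoids 9 rose (11 adjusted over the list alone), with a median of 2.06, and of 17 complement and coagulation genes 9 rose (11 rose and 1 fell adjusted over the list alone), with a median of 0.65. By camera the adjusted p values were 1.75e-07, 5.46e-05, 0.00149, 1.23e-09 and 7.09e-07 in that order of lists, and adjusted p = 0.141, 0.158, 0.108, 0.108 and 0.127 with an estimated correlation. The glucocorticoid list, which shares Lcn2 with the antimicrobial list, was set as a check and not on the treatment. Its rise therefore need not come from HDM.

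T cell, B cell and some endothelial markers were lower. Of 13 T cell markers 4 fell (9 adjusted over the list alone), with a median log2 fold change of -0.77. Cd8b1, a chain of the CD8 co-receptor, went from 8.96 ± 1.94 to 3.63 ± 0.666 FPKM (SD, n = 3) and Cd5 from 3.20 ± 0.665 to 1.35 ± 0.282. Neither Cd8b1 nor Cd5 was called without PBS_HDM 3 and Pam2ODN_HDM 3, the libraries with almost no Xist counts, where edgeR with Benjamini-Hochberg adjustment gave adjusted p = 0.0617 and 0.0604, the upper ends of ranges from 4.96e-06 and 2.36e-05 over the alternatives. Of 13 B cell markers 3 fell (10 adjusted over the list alone), with a median of -0.91. The complement receptor gene Cr2 lost its call without PBS_HDM 1, 2 or 3 (adjusted p = 0.102, 0.0944 and 0.0979 by edgeR with Benjamini-Hochberg adjustment) and without PBS_PBS 1, 2 or 3 (0.0757, 0.113 and 0.112), with a range of 0.00232 to 0.118 over all alternatives. Of 14 endothelial markers 4 fell (7 adjusted over the list alone), with a median of -0.33, among them the endothelin receptor gene Ednrb, from 15.6 ± 1.37 to 8.10 ± 0.642 FPKM (SD, n = 3). Other lymphocyte lists were not past camera's test. Markers of T helper activation and regulatory T cells were positive in 8 of 11 cases with 1 rise, also 1 adjusted over the list alone, and a median of 0.34 (adjusted p = 0.146). Cytotoxic and natural killer markers had 0 of 10 called by edgeR, also 0 adjusted over the list alone, at an unadjusted p under 0.05, by DESeq2 and by limma on FPKM, with a median of -0.19 (adjusted p = 0.355). For the T cell, B cell and endothelial lists camera gave adjusted p = 6.82e-05, 0.000293 and 0.0142, and adjusted p = 0.363, 0.514 and 0.303 with an estimated correlation.

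The largest falls were smaller than the largest rises. Hpcal4, a neuronal calcium sensor (ENSMUSG00000046093, chromosome 4, 123183227 to 123194701), fell by 2.32 ± 0.38 (SE) on the log2 scale, from 2.39 ± 0.483 to 0.451 ± 0.166 FPKM (SD, n = 3). The clock repressor Nr1d1 (ENSMUSG00000020889, chromosome 11, 98767932 to 98775333) went from 31.0 ± 5.21 to 7.39 ± 2.66 FPKM (SD, n = 3). Gpr34, a lysophosphatidylserine receptor of myeloid cells (ENSMUSG00000040229, chromosome X, 13632089 to 13640858), went from 4.06 ± 0.896 to 0.997 ± 0.158. Slitrk6, a neuronal membrane protein (ENSMUSG00000045871, chromosome 14, 110748580 to 110755149), went from 1.36 ± 0.221 to 0.317 ± 0.129 FPKM (SD, n = 3). These 4 genes were called under every alternative that was run. Nr1d1 belongs to the circadian list, which was set as a check on time of day.

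Pam2ODN_HDM was set against PBS_HDM to ask what the aerosol changed in lungs that later met HDM. Chil3 and Mgl2 were higher, and the interleukin-1 receptor antagonist Il1rn and the receptor Ffar2, which HDM had raised, were lower. Chil3, a chitinase-like protein of macrophages (ENSMUSG00000040809, chromosome 3, 106147554 to 106167564), was at 60.5 ± 6.41 FPKM in PBS_HDM and 156 ± 7.62 in Pam2ODN_HDM (SD, n = 3). Mgl2, a C-type lectin of macrophages and dendritic cells (ENSMUSG00000040950, chromosome 11, 70130329 to 70137550), was at 12.8 ± 2.00 and 25.2 ± 1.99 FPKM (SD, n = 3). Il1rn (ENSMUSG00000026981, chromosome 2, 24336853 to 24351494) was at 55.0 ± 6.37 and 26.7 ± 1.95 FPKM in the HDM groups (SD, n = 3).

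By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 7 genes were called, 4 higher and 3 lower, with adjusted p from 0.0403 to 0.0455. Among them were Slc1a2, a glutamate transporter (ENSMUSG00000005089, chromosome 2, 102658659 to 102790784), at 1.502 ± 0.19 (log2, SE), Tbxas1, thromboxane synthase (ENSMUSG00000029925, chromosome 6, 38875404 to 39084585), at 1.02 ± 0.12, and Ffar2, a receptor for short-chain fatty acids (ENSMUSG00000051314, chromosome 7, 30818348 to 30823775), at -1.81 ± 0.22. Log2 fold changes were 1.38 ± 0.14 for Chil3, 0.97 ± 0.12 for Mgl2 and -1.03 ± 0.13 for Il1rn (SE). The list of alternative macrophage activation, which holds Chil3 and Mgl2, was not past camera's test here, with 6 of 14 members positive and 8 negative, 2 called higher by edgeR (3 higher and 3 lower adjusted over the list alone), 2 higher and 3 lower by DESeq2, a median of -0.20 and a mean of 0.0118 (camera adjusted p = 0.929). At an unadjusted p under 0.05 there were 1555 genes, 786 higher and 769 lower, where 821 would come by chance, and complete separation held for 1916 genes (11.7%, where chance gives 10%). Each of the 7 genes kept its sign in every alternative, and the call held in 15 of 28 alternatives for Chil3, 14 for Ffar2 and Il1rn, 9 for Tbxas1, 7 for Mgl2 and 7 of 27 for Slc1a2. Over these alternatives the adjusted p of Chil3 ranged from 6.06e-16 to 0.564 and that of Mgl2 from 1.19e-09 to 0.605, and that of Ffar2, Il1rn, Slc1a2 and Tbxas1 reached 0.564. The counts of higher and lower genes were 32 and 56 without Pam2ODN_HDM 2, 0 and 2 without PBS_HDM 1, 0 and 1 without PBS_HDM 2, and 0 and 0 by edgeR without each of Pam2ODN_HDM 1 and 3, PBS_HDM 3 and PBS_PBS 1, 2 and 3, with 1146 to 2336 genes at an unadjusted p under 0.05 in the latter. With all libraries DESeq2 gave 178 and 198, and limma on FPKM 3 and 2. Limma on FPKM, the test fixed first, shared 3 calls with edgeR, those of Chil3, Il1rn and Ffar2. Its Benjamini-Hochberg adjusted p was 0.0716 for Mgl2, 0.0791 for Tbxas1 and 0.164 for Slc1a2.

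**Figure D2:**
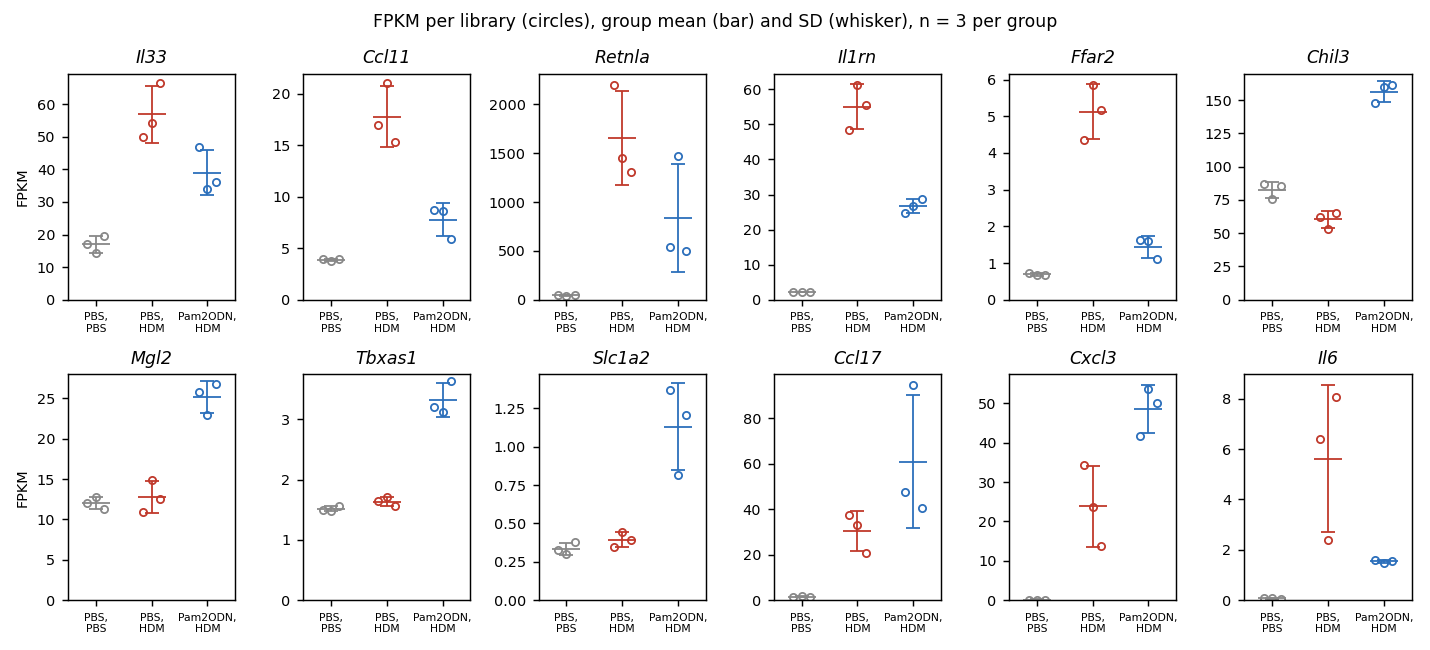
FPKM of 12 genes, chosen after their values were seen, in each library (circles) with the group mean (bar) and SD (whisker), n = 3 per group, for PBS_PBS (grey), PBS_HDM (red) and Pam2ODN_HDM (blue), on linear axes from 0. Il1rn and Ffar2 lie between the other groups in Pam2ODN_HDM (26.7 and 1.44 FPKM), while Chil3, Mgl2 and Tbxas1 are highest there (156, 25.2 and 3.32 FPKM).

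Acute inflammatory genes were lower as a group in Pam2ODN_HDM than in PBS_HDM. Of the 16 members 15 had a negative log2 fold change, with a median of -1.02, but 0 were called over all genes. Adjusted over the list alone 9 fell, at an unadjusted p under 0.05 there were 11 lower and 1 higher, DESeq2 called 9 lower and limma on FPKM called 0. Il6 was at 5.62 ± 2.92 FPKM in PBS_HDM and 1.55 ± 0.0513 in Pam2ODN_HDM (SD, n = 3), Cxcl1 at 52.1 ± 7.95 and 23.3 ± 2.78, Csf3 at 4.79 ± 1.32 and 1.02 ± 0.379, and Il1b at 217 ± 45.0 and 101 ± 13.1. The exception, named after its values were seen, was Cxcl3, at 23.8 ± 10.3 and 48.5 ± 6.12 FPKM (SD, n = 3). All 20 type I interferon response genes had a negative log2 fold change, with a median of -0.63, which was -0.41 without Pam2ODN_HDM 1 and -0.87 without PBS_HDM 3. Their mean log2(FPKM + 0.1) was 4.19, 4.32 and 3.61 in PBS_HDM 1, 2 and 3 and 3.13, 3.51 and 3.57 in Pam2ODN_HDM 1, 2 and 3, so that PBS_HDM 3, a library with almost no Xist counts, lay closer to Pam2ODN_HDM 2 and 3 than to the rest of its group. None was called by edgeR over all genes and 8 fell adjusted over the list alone, with 12 lower at an unadjusted p under 0.05, 4 lower by DESeq2 and 0 by limma on FPKM. Rsad2 was at 10.1 ± 2.21 FPKM in PBS_HDM and 4.40 ± 0.886 in Pam2ODN_HDM (SD, n = 3). For Toll-like receptor and NF-kB pathway genes 18 of 20 were negative, with a median of -0.29, 0 called and 4 lower adjusted over the list alone, 9 lower and 1 higher at an unadjusted p under 0.05, 2 lower by DESeq2 and 0 by limma. The camera test gave adjusted p = 6.5e-12, 6.5e-12 and 2.34e-06 for the acute, interferon and Toll-like receptor lists, and adjusted p = 0.111, 0.212 and 0.212 with an estimated correlation.

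Alveolar macrophage markers were higher in Pam2ODN_HDM, positive in 10 of 12 cases with a median log2 fold change of 0.74. Over all genes 0 were called by edgeR, 8 rose adjusted over the list alone, 9 were higher at an unadjusted p under 0.05, 7 by DESeq2 and 1 by limma on FPKM. The protease gene Ctsk (ENSMUSG00000028111, chromosome 3, 95499256 to 95509362) was at 30.7 ± 3.34 FPKM in PBS_HDM and 71.8 ± 9.76 in Pam2ODN_HDM (SD, n = 3). All 11 genes of antigen presentation by MHC class II had positive values, with a median of 0.76, 0 called and 0 adjusted over the list alone, 8 higher at an unadjusted p under 0.05 and 0 by DESeq2 and limma. H2-Eb1, an MHC class II chain, was at 109 ± 34.0 and 203 ± 48.1 FPKM (SD, n = 3). Markers of alveolar type 2 cells, the surfactant-producing epithelium, were positive in 12 of 12 cases with a median of 0.47, 0 called, 4 higher adjusted over the list alone, 7 higher at an unadjusted p under 0.05, 2 by DESeq2 and 0 by limma. The surfactant protein gene Sftpb was at 791 ± 152 and 1187 ± 106 FPKM (SD, n = 3). For these 3 lists camera gave adjusted p = 6.31e-09, 2.97e-08 and 2.34e-06, and adjusted p = 0.111, 0.212 and 0.212 with an estimated correlation.

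In total 26 of 38 lists were past camera's test in this comparison, 11 higher and 15 lower in Pam2ODN_HDM, and 0 with an estimated correlation, where the lowest adjusted p by camera was 0.111. Among the 26 were red blood cell, cardiac muscle, immediate early, glucocorticoid-responsive and mitochondrially encoded genes, lists set as checks on dissection, blood and handling. A call with the preset correlation thus does not by itself show an effect of the aerosol. Of 9 cardiac and 13 mitochondrially encoded genes 0 were called by edgeR, DESeq2 or limma on FPKM. The cardiac call was lost without PBS_HDM 2, among others (camera adjusted p = 0.292). Of the 26, 13 kept their call with each library left out in turn. Among those 13, plasma cell and immunoglobulin genes had a median log2 fold change of 0.75, immediate early genes -0.75, glucocorticoid-responsive genes -0.81, epithelial antimicrobial genes -0.45, interferon-gamma response genes -0.39 and genes of mucous metaplasia -0.37. Their adjusted p values by camera were 2.79e-07, 8.61e-06, 8.61e-06, 0.000143, 0.000426 and 0.000782, and adjusted p = 0.253, 0.253, 0.212, 0.212, 0.253 and 0.253 with an estimated correlation. Of their 13, 12, 12, 13, 21 and 10 measured members, 0, 0, 0, 1, 0 and 0 were called by edgeR over all genes and by limma on FPKM, 0, 2, 1, 2, 5 and 1 adjusted over the list alone, 3, 4, 2, 3, 8 and 3 at an unadjusted p under 0.05, and 1, 2, 1, 2, 3 and 1 by DESeq2. The antimicrobial list member called by edgeR and limma was Il1rn, the interleukin-1 receptor antagonist already named above. Red blood cell genes were negative in 8 of 8 cases, with 0 called by edgeR, 6 lower adjusted over the list alone and at an unadjusted p under 0.05, 3 lower by DESeq2, 0 by limma on FPKM and a median of -0.64 (camera adjusted p = 1.44e-08, and adjusted p = 0.212 with an estimated correlation). Haemoglobin genes took 1.67%, 2.85% and 1.94% of the counts in Pam2ODN_HDM 1, 2 and 3 and 3.58%, 3.10% and 2.68% in PBS_HDM 1, 2 and 3. Neutrophil markers had a median of -0.38, with 0 of 13 called by edgeR, 5 lower adjusted over the list alone, 5 lower and 1 higher at an unadjusted p under 0.05 4 lower by DESeq2 and 0 by limma on FPKM (camera adjusted p = 0.000158, and adjusted p = 0.253 with an estimated correlation). The neutrophil call was lost without Pam2ODN_HDM 1 (camera adjusted p = 0.0847). With 1 library left out the median of neutrophil markers went from -0.0937 (without Pam2ODN_HDM 1) to -1.15 (without Pam2ODN_HDM 2), that of antimicrobial genes from -0.26 (without Pam2ODN_HDM 1 or 3) to -1.13 (without Pam2ODN_HDM 2), and that of plasma cell genes from 0.49 (without PBS_HDM 3) to 1.22 (without PBS_HDM 1). It was -0.41 for glucocorticoid-responsive genes without Pam2ODN_HDM 3, -0.24 for interferon-gamma response genes without PBS_HDM 2 and -0.18 for genes of mucous metaplasia without PBS_HDM 1.

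**Figure D3:**
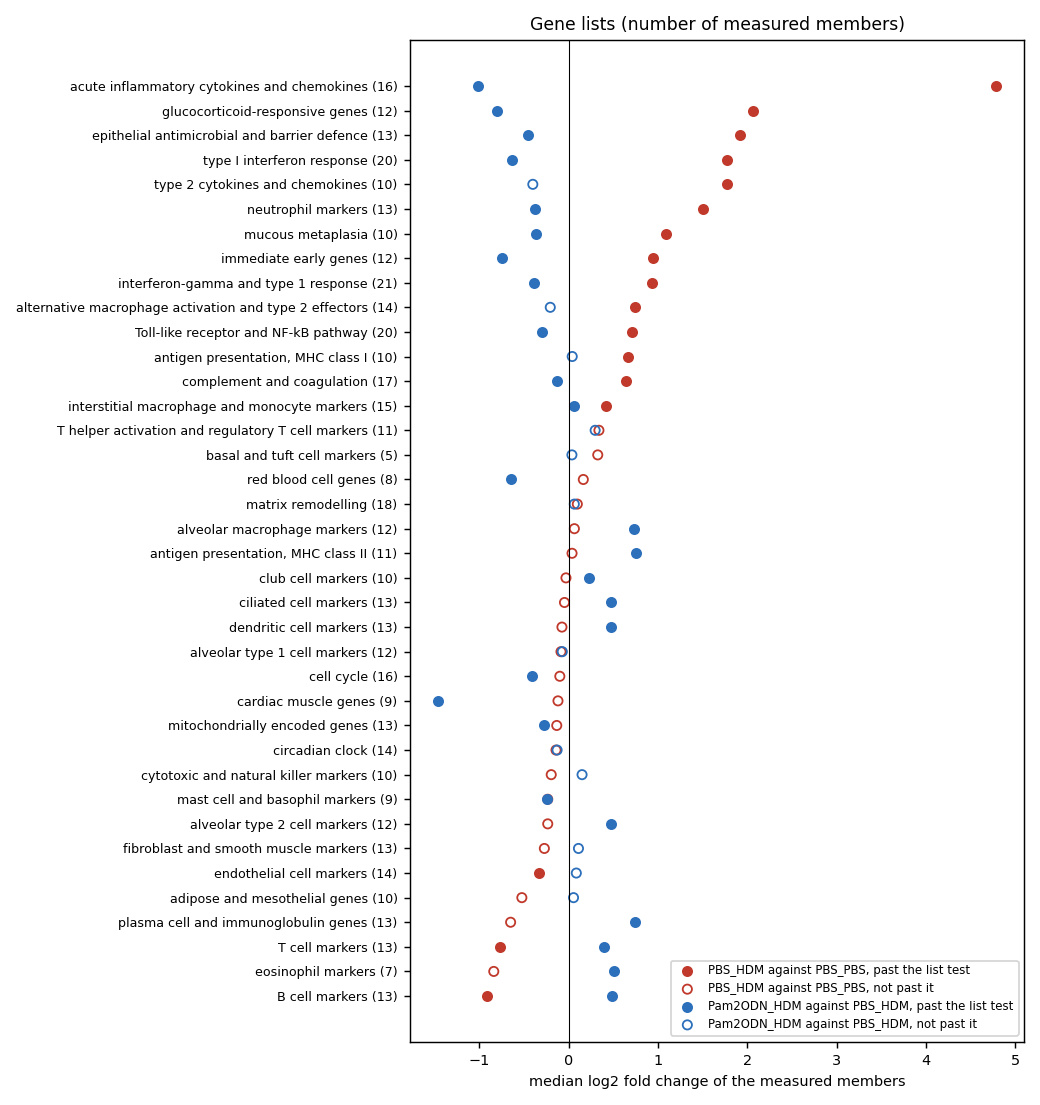
Median log2 fold change of the measured members (number in parentheses) of 38 gene lists, 1 line per list, for PBS_HDM against PBS_PBS (red) and Pam2ODN_HDM against PBS_HDM (blue), filled where camera's adjusted p with the preset correlation is under 0.05 and open otherwise. Acute inflammatory genes lie at 4.79 and -1.02, and alveolar macrophage markers at 0.06 and 0.74.

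Genes of type 2 inflammation were less uniform between the HDM groups. The type 2 cytokine and chemokine list had a median log2 fold change of -0.40 with 0 of 10 called by edgeR, 2 higher and 3 lower adjusted over the list alone, 2 higher and 4 lower at an unadjusted p under 0.05, 1 higher and 1 lower by DESeq2 and 0 by limma, and it was not past camera's test (adjusted p = 0.217). Ccl22 was at 28.8 ± 3.18 FPKM in PBS_HDM and 64.5 ± 9.87 in Pam2ODN_HDM (SD, n = 3), and the chemokine Ccl8 at 23.3 ± 5.41 and 10.5 ± 4.26. Ccl11 was at 17.8 ± 2.96 and 7.75 ± 1.61 FPKM (SD, n = 3), a log2 fold change of -1.19 ± 0.22 (SE) with adjusted p = 0.135 by edgeR with Benjamini-Hochberg adjustment. Ccl11 was called without Pam2ODN_HDM 2 (adjusted p = 0.0397 by edgeR with Benjamini-Hochberg adjustment), without that library and PBS_HDM 1 (0.0443), with the length trend removed (0.0469), by DESeq2 (0.000111) and by voom (0.00775), with a range of 0.000111 to 0.564 over the alternatives. Il33 was at 56.9 ± 8.68 and 39.0 ± 6.93 FPKM (SD, n = 3), with -0.55 ± 0.15 (SE) and adjusted p = 0.259 by edgeR with Benjamini-Hochberg adjustment, in a range of 0.0317 (voom) to 0.977 over the alternatives. Retnla was at 1655 ± 479 and 835 ± 555 FPKM (SD, n = 3), with -0.93 ± 0.46 (SE) and adjusted p = 0.58 by that edgeR test with Benjamini-Hochberg adjustment, and without Pam2ODN_HDM 2 it was called at -1.78 (adjusted p = 0.0337), as it was at -1.47 without that library and PBS_HDM 1 (0.0251), in a range of 0.0129 (voom) to 0.979. For Il4, Tslp, Ccl24 and Clca1 the log2 fold changes were 0.69, -0.25, -0.87 and -0.22, with adjusted p = 0.596, 0.792, 0.678 and 0.926 by the edgeR test with Benjamini-Hochberg adjustment. Without Pam2ODN_HDM 2 the value for Ccl24 was -1.73, and without Pam2ODN_HDM 1 that for Clca1 was -1.56, neither of them called.

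The genes that HDM moved were followed into the comparison of Pam2ODN_HDM with PBS_HDM, to ask whether the aerosol shifted them back. Of the 1830 genes called in PBS_HDM against PBS_PBS, 1667 (91.1%) had the opposite sign in Pam2ODN_HDM against PBS_HDM, 1072 of the 1205 that rose (89.0%) and 595 of the 625 that fell (95.2%). At an unadjusted p under 0.05, 706 moved in the opposite and 21 in the same direction, and 3, Il1rn and Ffar2 among them, were called opposite and 0 the same. The comparisons share the PBS_HDM libraries with opposite sign. In 20 simulated data sets with Pam2ODN_HDM drawn from the PBS_HDM means, the share was 64.4% on average (62.3% to 66.3%) and 163 genes were opposite at an unadjusted p under 0.05 (191 at most). In 20 data sets with all groups unchanged no gene was called by edgeR in PBS_HDM against PBS_PBS, and among the 1830 genes with the smallest p 86.0% had opposite signs (87.2% at most). The covariance of the log2 fold changes of both comparisons was -0.139 across genes, against -0.063 and -0.064 in the simulations. The median ratio of the change of Pam2ODN_HDM from PBS_PBS to that of PBS_HDM from PBS_PBS was 0.70 for genes that rose and 0.59 for genes that fell, where the simulation with the PBS_HDM means gave 0.94 and 0.87. The simulations drew each gene independently. In the real data many genes deviated together, as in Pam2ODN_HDM 2 and PBS_HDM 1, whose deviations from their group means correlated at 0.53 across genes. The simulated ranges may therefore be too narrow as a measure of chance. With 3 libraries the shared group cannot be split into parts of at least 2, so part of the excess may come from the shared libraries. Leaving out Pam2ODN_HDM 1 gave a share of 82.4%, and leaving out Pam2ODN_HDM 3 gave 84.6%.

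Pam2ODN_HDM was last compared with PBS_PBS, to ask how lungs given both agents differed from lungs given neither. Cbln1, a secreted protein known from cerebellar synapses (ENSMUSG00000031654, chromosome 8, 87468405 to 87472609), had 0 counts in PBS_PBS and an FPKM of 2.20 ± 0.729 (SD, n = 3) in Pam2ODN_HDM, at least 160-fold higher. Csf3 was at least 34.8-fold higher, and Saa3 and Cxcl3 had log2 fold changes of 8.99 and 8.88. Ccl17 went from 1.60 ± 0.146 to 60.9 ± 29.3 FPKM (SD, n = 3), a log2 fold change of 5.38. Without Pam2ODN_HDM 2 the values of Saa3 and Ccl17 were 7.91 and 4.78, and both stayed called. Tnfrsf9, a co-stimulatory receptor of T cells, rose by 5.05 ± 0.38 (SE) on the log2 scale. Of the genes that fell, Chrdl1, a secreted antagonist of bone morphogenetic proteins (ENSMUSG00000031283, chromosome X, 143285674 to 143394262), went from 3.79 ± 0.510 to 1.25 ± 0.472 FPKM (SD, n = 3), a log2 fold change of -1.53. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 626 genes were called, 561 higher and 65 lower, 381 and 17 of them at least 2-fold, and the groups were completely separated for 4615 genes (28.1%, where chance gives 10%). The count of higher genes was 269, 313 and 255 without PBS_PBS 1, 2 and 3. The count of lower genes was 5, 9 and 5 without PBS_PBS 1, 2 and 3, and 36 and 35 without PBS_HDM 2 and 3.

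Of the 16 acute inflammatory genes 13 rose from PBS_PBS to Pam2ODN_HDM (15 adjusted over the list alone), with a median log2 fold change of 4.01, also with genes at 0 set to their bound. Cxcl1 was at 1.19 ± 0.409 and 23.3 ± 2.78 FPKM (SD, n = 3). Antimicrobial and barrier genes rose in 9 of 13 cases, also 9 adjusted over the list alone, with a median of 1.91, and Lcn2 was at 20.8 ± 0.574 and 796 ± 274 FPKM (SD, n = 3). Of 10 type 2 cytokines and chemokines 5 rose, also 5 adjusted over the list alone, with a median of 0.77, and Ccl22 went from 4.04 ± 0.553 to 64.5 ± 9.87 FPKM (SD, n = 3). Alternative macrophage activation genes rose in 7 of 14 cases and fell in 1 (9 and 2 adjusted over the list alone), with a median of 0.64. Among them Mgl2 went from 12.1 ± 0.709 to 25.2 ± 1.99 and Chil3 from 82.6 ± 6.00 to 156 ± 7.62 FPKM (SD, n = 3). For these 4 lists camera gave adjusted p = 1.03e-24, 3.31e-12, 1.8e-05 and 1.23e-05, and they were the lists that passed with an estimated correlation (adjusted p = 0.0336, 0.0407, 0.0407 and 0.0407). In all, 28 of 38 lists passed with the preset correlation, 20 higher and 8 lower. Il33 and Retnla were higher than in PBS_PBS by 1.28 ± 0.15 and 4.39 ± 0.53 (log2, SE), with adjusted p = 0.00138 and 0.00156 by edgeR with Benjamini-Hochberg adjustment. Ccl11 was higher by 1.10 ± 0.22 (SE) with adjusted p = 0.0256, and its call was lost without Pam2ODN_HDM 1 (adjusted p = 0.0544) and PBS_PBS 1, 2 and 3 (0.105, 0.101 and 0.106), in a range of 0.000116 to 0.106 by edgeR and the other tools with Benjamini-Hochberg adjustment. Il4, Tslp, Ccl24 and Clca1 were not called, with log2 fold changes of 0.20, -0.48, 0.45 and 2.21. Clca1 was at 0.88 without Pam2ODN_HDM 1, and Ccl24 changed sign to -0.43 without Pam2ODN_HDM 2, neither of them called. Without Pam2ODN_HDM 2 the rise of Retnla was 3.53 on the log2 scale.

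Myeloid markers beyond the alveolar compartment were also higher in Pam2ODN_HDM than in PBS_PBS. Of 15 interstitial macrophage and monocyte markers 6 rose (8 adjusted over the list alone), with a median log2 fold change of 1.04, and Ms4a7, a membrane protein of macrophages, went from 1.26 ± 0.132 to 4.04 ± 0.945 FPKM (SD, n = 3). Of 12 alveolar macrophage markers 5 rose (6 adjusted over the list alone), with a median of 0.85, and Ctsk went from 14.5 ± 1.21 to 71.8 ± 9.76 FPKM (SD, n = 3). Of 20 type I interferon response genes 9 rose (15 adjusted over the list alone), with a median of 1.19. The camera test gave adjusted p = 5.64e-06, 4.53e-05 and 5.87e-11 for these 3 lists, and adjusted p = 0.145, 0.145 and 0.197 with an estimated correlation. Between the 2 comparisons with PBS_PBS, 488 genes were called higher in both, 56 lower in both and 0 in opposite directions by edgeR, where independent lists of these sizes would share 41.2 and 2.47. The covariance of the log2 fold changes was 0.333 across genes, against 0.064 in simulations with all groups unchanged. Those simulations called no gene in PBS_HDM against PBS_PBS, so they could share no call and cannot serve as a measure of the overlap. Simulations with Pam2ODN_HDM drawn from the PBS_HDM means gave a mean covariance of 0.5001. On average they called 1098.4 genes higher in both and 639 lower in both. The shared PBS_PBS libraries cannot be split into parts of at least 2, so part of the observed overlap may come from them.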

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

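In this part, the tests of the length trend in each of 2 libraries, of library depth, of a male mouse and of a single X chromosome were chosen only after their result was seen, and the reading of the bound for the mix of cell types was changed after its value was known. No group had 4 to 10 libraries, so no library was tested as an outlier. Among 15160 genes left out of the comparisons for low values, a search for at least 1000 counts in 1 library with at most 3 in each PBS_PBS library found the following genes.

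In PBS_HDM 3 the Y-linked genes Kdm5d, Ddx3y and Eif2s3y had 1266, 3830 and 2704 counts, against 0 in each other library. Gm20716, a gene model across Adnp and Dpm1 (chromosome 2, 168180986 to 168230364), had 3336 counts in Pam2ODN_HDM 2 and 3901 in PBS_HDM 1, and Adnp itself had 0 and 1225 counts there against 4287 to 6734 in the other libraries. Gm29253, a model across Abcb6 and Atg9a (chromosome 1, 75171731 to 75185146), had 2196 counts in Pam2ODN_HDM 2, where Atg9a had 842. Gm45062, a model across Umad1 and Glcci1 (chromosome 6, 8259450 to 8597480), had 1617 counts in PBS_HDM 2, where Glcci1 had 44 against 884 to 2892 elsewhere.

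The first pattern is the near absence of Xist from PBS_HDM 3 (8 counts) and Pam2ODN_HDM 3 (5 counts). For PBS_HDM 3 the sum of 8580 counts over 4 Y-linked genes is what a male mouse would give. For Pam2ODN_HDM 3 the sum of 0 argues against a male, and a median ratio of 0.891 for 3 long nuclear RNAs to the libraries with Xist argues against a general loss of such RNA. A single X chromosome may account for it, but this stays open. The 4 genes that escape X inactivation had a median ratio of 0.635, while only 2 of them, Kdm6a and Eif2s3x, lay below all 7 libraries with Xist. That count cannot decide, since in PBS_HDM 3, the library with Y-linked counts, only 1 of them lay below all 7. For Kdm6a, Eif2s3x, Kdm5c and Ddx3x the ratios were 0.508, 0.596, 0.690 and 0.673 in Pam2ODN_HDM 3. In PBS_HDM 3 they were 0.565, 0.731, 0.772 and 0.951. The sex of the mice is not given by the labels, so no biological explanation from the design was tested.

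The second pattern is that Pam2ODN_HDM 2 and PBS_HDM 1 stand apart, the former with the lowest mean correlation to its own group (0.940, against 0.954 or more for the other 7 libraries). After removal of the trend with transcript length Pam2ODN_HDM 2 was at 0.945 and the lowest of the others at 0.958, which argues against that trend as the whole cause there, while it stays open for PBS_HDM 1, within the range of the others before (0.963) and after (0.965). Depth is argued against, since the lower total count of the pair was 1.18 times the lowest of the others. Another mix of cell types could contribute and stays open, since Pam2ODN_HDM 2 lay outside the range of the other libraries in 4 of 19 cell type lists, under the 4.22 of chance that was set in advance as the bound against it, but by less than the spread between libraries (1 to 7). The groups do not separate these libraries from the rest, so no biological explanation was tested.

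Other groupings of the same 6 libraries were tested for each comparison, and 10 splits are too few for a share under 0.05. PBS_HDM against PBS_PBS gave 1830 genes in the real split and at most 0 by edgeR in the others. Pam2ODN_HDM against PBS_HDM gave 7 and at most 2, and Pam2ODN_HDM against PBS_PBS gave 626 and at most 0, so that only 1 split, the real one, reached the real count in each comparison. Every other split mixed libraries of both groups, so that a real difference between the groups widened the spread within them. Few calls were therefore likely there from the start, and these counts cannot decide on chance.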

How the results depend on the processing

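Limma on FPKM with pseudocount 0.1 was the test fixed first, and it became an alternative once the data had been seen to hold counts. Chosen only after the data had been seen were edgeR as the test for single genes and the tests with DESeq2, no scaling, voom with quality weights, removal of the length trend and omission of the pair Pam2ODN_HDM 2 and PBS_HDM 1 or the pair PBS_HDM 3 and Pam2ODN_HDM 3. No called result reversed its direction under any alternative. Depth limits genes near the FPKM filter. Settings of pseudocount, FPKM scaling, trend and limma's robust spread were fitted with limma on FPKM, so they differ from the edgeR counts in the test as well, and the counts of limma with pseudocount 0.1 are given for them. In PBS_HDM against PBS_PBS limma on FPKM with pseudocount 0.1 placed the median log2 fold change of all genes at -0.107, in a range of -0.128 (rescaled to the same sum) to -0.0547 (quantile scaling) over the other fits on FPKM, and in Pam2ODN_HDM against PBS_PBS it was -0.144 with the same rescaling. The cause of the differences below was not tested unless given.

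For PBS_HDM against PBS_PBS (1205 higher, 625 lower), limma on FPKM gave 971 and 664, with FPKM rescaled to the same sum 800 and 374 and with quantile scaling 1174 and 950. By edgeR no filter gave 372 lower with more genes tested, a fit of only the 2 groups 1912 and 1298, and a 2-fold minimum 622 and 229. DESeq2 gave 1291 lower, voom 2596 and 2209, removal of the length trend 1003 lower, omission of Pam2ODN_HDM 2 and PBS_HDM 1 1997 and 1438, and omission of PBS_HDM 3 and Pam2ODN_HDM 3 732 and 228. Leaving out 1 library gave 627 (without PBS_PBS 3) to 2006 (without Pam2ODN_HDM 2) higher and 187 to 1457 lower, from the same libraries.

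For Pam2ODN_HDM against PBS_HDM (4 higher, 3 lower), edgeR gave 0 and 0 with no filter (1966 genes at an unadjusted p under 0.05), with only the 2 groups (1107) and without PBS_HDM 3 and Pam2ODN_HDM 3 (810). Limma on FPKM gave 3 and 2, without the trend 0 and 0 (1462 at an unadjusted p under 0.05), with FPKM rescaled to the same sum 3 and 0 (1243), and with pseudocount 1 it gave 6 and 7. DESeq2 gave 178 and 198, voom 310 and 320, removal of the length trend 15 and 25, and omission of Pam2ODN_HDM 2 and PBS_HDM 1 87 and 100. Leaving out 1 library gave 0 to 32 higher and 0 to 56 lower, the highest without Pam2ODN_HDM 2.

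For Pam2ODN_HDM against PBS_PBS (561 higher, 65 lower), only the 2 groups gave 348 and 13, DESeq2 1161 and 432, voom 1096 and 488, and omission of PBS_HDM 3 and Pam2ODN_HDM 3 343 and 31. By limma on FPKM the lower count was 48, with pseudocount 0.01 and with robust spread 43, with FPKM rescaled to the same sum 15 and with quantile scaling 141. By edgeR it was 21 with no filter, 17 with a 2-fold minimum, 168 with the length trend removed and 153 without Pam2ODN_HDM 2 and PBS_HDM 1. Leaving out 1 library gave 255 (without PBS_PBS 3) to 574 higher and 5 (without PBS_PBS 1 or 3) to 92 lower.

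The library numbers were not taken to pair the samples, since nothing in the sources used here says that they do. Libraries of the same number had deviations that correlated at -0.51 to 0.27 across genes. Those of different numbers correlated at -0.37 to 0.53, so this check cannot exclude a pairing. With the number as a replicate block, the lower count was 395 for PBS_HDM against PBS_PBS and 38 for Pam2ODN_HDM against PBS_PBS, and edgeR called 0 higher and 0 lower for Pam2ODN_HDM against PBS_HDM (1327 at an unadjusted p under 0.05).

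With the correlation between genes estimated, camera called 3, 0 and 4 lists in the 3 comparisons, where the preset correlation gave 17, 26 and 28. Leaving out 1 library gave 17 to 22, 19 to 26 and 24 to 28 lists. Of the named genes called, 83 to 111 of 111, 0 to 7 of 7 and 51 to 81 of 81 kept their call in each alternative, and 0 reversed. The opposite-direction share was 83.5% with only the 2 groups in the fit, and 82.4% (without Pam2ODN_HDM 1) to 94.7% (without Pam2ODN_HDM 2) with 1 library left out.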

Other observations

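The tests of KEGG terms and of the length trend and omitted pairs below were chosen only after results had been seen. Of 14 circadian clock genes 1 rose and 5 fell with HDM (3 and 6 adjusted over the list alone), with a median log2 fold change of -0.14 that was not past camera's test (adjusted p = 0.43). Camera tests for a shift in 1 direction, so it cannot decide on a list whose members moved both ways. DESeq2 called 3 of them higher and 6 lower. The list was set as a check on time of day, and a part of time of day in these changes stays open. Bhlhe40, a repressor of the clock that also acts in immune cells, went from 10.9 ± 0.480 to 34.6 ± 2.36 FPKM (SD, n = 3), and Nr1d1 from 31.0 ± 5.21 to 7.39 ± 2.66. Of 18 genes of matrix remodelling 5 rose (5 rose and 1 fell adjusted over the list alone), among them Timp1, an inhibitor of metalloproteinases, from 7.76 ± 1.19 to 247 ± 29.7 FPKM (SD, n = 3), and the macrophage elastase Mmp12 from 1.17 ± 0.115 to 5.18 ± 1.57, with a list median of 0.10 (camera adjusted p = 0.0688). Fibroblast and smooth muscle markers had 1 rise and 4 falls of 13 (2 and 5 adjusted over the list alone), and Wnt2, a growth factor of lung mesenchyme, went from 16.4 ± 1.71 to 7.40 ± 1.55 FPKM (SD, n = 3), with a median of -0.27 (camera adjusted p = 0.121).

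Of 7 eosinophil markers 1 rose and 2 fell with HDM (1 and 3 adjusted over the list alone), with a median log2 fold change of -0.84 (camera adjusted p = 0.0891). Ear1, an eosinophil-associated ribonuclease gene whose close paralog Ear2 may share its reads, was at 26.2 ± 4.63 FPKM in PBS_PBS, 6.83 ± 1.18 in PBS_HDM and 19.7 ± 6.84 in Pam2ODN_HDM (SD, n = 3). The list members Epx, Prg3 and Il5ra lay under the filter, and which cells gave the Ear1 reads was not tested. The values therefore do not show a change in the number of eosinophils. Of 288 KEGG terms over 5606 annotated genes, cytokine-cytokine receptor interaction held 68 of the 612 annotated genes that rose with HDM, where 20.96 of its 192 genes would by chance (one-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 9.73e-18). For genes that fell the lowest adjusted p in that Fisher's exact test was 0.114. In Pam2ODN_HDM against PBS_PBS the same term held 50 of 297 higher genes, where 10.2 would by chance (adjusted p = 5.21e-20 by the same Fisher's exact test). That test treats genes as independent, so its p-values do not measure the spread between libraries and may be too small.

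A hypothesis from these data is that the aerosol may lower the acute inflammatory response of the lung to HDM, since the 16 genes of that list had a median log2 fold change of -1.02 in Pam2ODN_HDM against PBS_HDM. The technical sources tested, on all 16 members, were the length trend and 2 pairs of libraries. The median was -1.08 with the length trend removed, -0.96 without Pam2ODN_HDM 2 and PBS_HDM 1 and -1.003 without PBS_HDM 3 and Pam2ODN_HDM 3, and the difference of the list's mean per library was -1.09 ± 0.13, -0.96 ± 0.13 and -1.10 ± 0.28 (SE), with 15 of 16 members negative each time, which argues against each of these as the whole source. Of the members 3, 4 and 0 were called lower in those fits by edgeR, and the list's adjusted p by camera was 0.111 with an estimated correlation. Handling and blood content were not tested as sources and stay open. The check lists of immediate early, glucocorticoid-responsive and red blood cell genes were also lower as groups, past camera's test only with the preset correlation. A smaller share of neutrophils stays open, since their markers had a median of -0.38 (-0.0937 without Pam2ODN_HDM 1 and -1.15 without Pam2ODN_HDM 2) and adjusted p = 0.253 by camera with an estimated correlation. No group received the aerosol without HDM, and an experiment with such a group and with counts of neutrophils in the same lungs would test the hypothesis.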
